A study of Rattus norvegicus with 32 samples.

How the data were processed

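RNA was measured in 32 liver samples of male F344 rats with 1-colour Agilent arrays. Per the labels' protocols, rats received furan by gavage on 5 days per week for 104 weeks, at 0.92 or 2 mg per kg body weight, or vehicle. Livers were taken 24 hours after the last dose, and Cy3-labelled cRNA was made from 0.5 µg of total RNA. Samples were grouped by the labels into vehicle control liver (n = 5) and 3 kinds of tissue from furan-treated rats: liver without a lesion (NT), liver without a lesion next to one (ANT) and cholangiofibrotic lesion tissue (TRT). Each of these had 4 samples at 0.92 mg and 5 samples at 2 mg. Most labels give an age of 110 weeks, while control replicate 5 also carries 111 weeks and TRT 0.92 mg replicate 4 also carries 118 weeks. The labels do not say how many rats gave the samples, so p-values measure the spread between these samples.

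The authors deposited 1 table of linear intensity values for 62976 features on each array. Per the submitters' processing notes, signals were extracted with Agilent Feature Extraction 10.7. The background correction, the scaling step and any filter are not given in the sources used here. In the deposited intensity values the 75th percentile of every array lay at 1000 and no value was 0 or negative, so the values had been scaled between arrays but not put on a log scale or centred per feature. Arrays are 1-colour, so the direction of each difference is that of the groups as named. Median intensities in replicates 1 to 5 were 77.4, 76.2, 93.2, 101.1 and 84.5 in control. They were 73.2, 78.7, 95.6 and 92.8 in NT, 81.0, 84.0, 99.2 and 94.1 in ANT, and 128.6, 103.8, 105.9 and 120.3 in TRT at 0.92 mg. At 2 mg they were 81.4, 79.1, 80.1, 79.4 and 81.2 in NT, 85.6, 75.7, 91.3, 86.8 and 83.8 in ANT, and 110.5, 114.1, 129.8, 105.2 and 90.5 in TRT. Between 33.1% and 38.9% of the features of an array lay below an intensity of 20, a range treated here as a low plateau. The level of 20 was set here, and whether levels below it can be ranked was not tested. The number of arrays limits the precision. No 2 columns were identical, and the highest correlation between 2 arrays was 0.994.

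The table's rows carry feature numbers and no probe or gene name, and the reference table used here has no column that pairs with them. Results are therefore given per feature, several features can measure 1 gene, and control features, whose numbers are not known here, stayed among the features tested. The fixed gene lists, the planned choice of 1 probe per gene and the mean over a gene's probes could not be run for this reason. At most 2 numbers of features that rose and 2 that fell are printed. These are the first 2 of each direction under the rule for single features in TRT 2 mg against control. Features 7740 and 43145 were preferred to those with the largest falls in TRT against NT at 2 mg, which were dimmer, after the values had been seen.

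Values were taken as log2 intensity minus the array's 75th percentile. Each comparison was fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with lmFit and eBayes with a mean-variance trend and robust settings, on the arrays of the 2 groups compared, without a block and without a filter on dim features. All adjusted p-values of single features are limma's with Benjamini-Hochberg adjustment over the 62976 features, and a feature was called at an adjusted p under 0.05. The difference between doses in the TRT and NT contrast was tested as an interaction in 1 fit of 4 groups. Features described singly were taken from the features called whose samples did not overlap between the groups and whose brighter group was at or above the median of all features, up to 10 per direction by log2 fold change. Where a group lay on the plateau, the fold is given as a bound, with values under 20 set to 20. A feature was counted as on in a group if all its arrays reached 100, and as off if all its arrays lay below 20. Shares of signal per array were compared with exact 2-sided permutation tests.

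The fit was tested on 1 draw of simulated data per comparison, with 200 changed features, 100 at each size. All changed features were drawn from those at or above the median level, so recovery among dimmer features was not tested. Each feature had its mean over all 32 arrays in both groups, the spreads of the real groups and normal noise independent of other features. In NT 2 mg against control it recovered 47.0% of changes of 2-fold and 83.0% of changes of 4-fold, and 21 of 151 calls were false. In NT 0.92 mg against control it recovered 19.0% and 59.0%, with 4 of 82 calls false. In ANT against NT at 2 mg it recovered 66.0% and 95.0%, with 17 of 178 calls false. In TRT against control it recovered 14.0% and 61.0% at 0.92 mg, with 18 of 93 calls false, and 23.0% and 68.0% at 2 mg, with 11 of 102 calls false. In 4 of these 5 tests more than 5% of the calls were false, so the counts of calls may hold more false ones than the threshold names. Real features are not independent and the number that changed is not known, so these shares cannot be carried over to the real counts.

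Samples in NT, ANT and TRT share replicate numbers, and the labels do not say that a number marks a rat. Deviations from the group means were correlated between same-numbered arrays across features. For ANT and NT every pair was above 0.1, from 0.568 to 0.679 at 0.92 mg and from 0.206 to 0.367 at 2 mg. The same held for TRT and ANT at 2 mg, from 0.148 to 0.329. At 0.92 mg replicates 3 and 4 of NT and ANT belong to a set of 8 arrays that stood apart, described below, which can by itself raise these correlations. Each ANT array correlated best with the NT array of its own number, in 4 of 4 at 0.92 mg and 5 of 5 at 2 mg. The numbers of ANT and NT, and of TRT and ANT at 2 mg, were taken to pair the samples, on the basis of the correlations. For the other comparisons within a dose at least 1 pair fell below 0.1. At 2 mg, numbers that pair ANT with NT and TRT with ANT would also pair TRT with NT. The correlations of TRT and NT did not meet the rule, so their main tests at 2 mg were run without pairs. If these pairs hold, those tests ignore them.

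The alternatives chosen before the data were examined were 1 fit of all 32 arrays, quantile normalization, median centring, a filter that kept features with a mean above the 40th percentile, the replicate number as a block, and leaving out each array in turn. Those added after seeing the data were 2 versions of a floor at 20, a set of 8 arrays that stood apart as a block or with only arrays inside or outside it, 2 lesion arrays left out together, other levels for on features, and other sizes of the brightest class and of the feature sets of a lesion score. In the first version of the floor, values were raised to 20 before the scaling and all features were kept. The second, which scales first and leaves out features at the floor on every array compared, was written after the result of the first had been seen, and both are reported. The set of 8 arrays was picked by eye from a plot of principal components and then defined as the lowest 8 arrays on the second one.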

Results

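The data describe gene expression in the livers of male F344 rats, an inbred strain, after long-term oral exposure to furan, a small heterocyclic compound. Livers of vehicle-treated rats were the control (n = 5 samples). From furan-treated rats, NT (liver without a lesion), ANT (liver without a lesion next to one) and TRT (cholangiofibrotic tissue, in which bile-duct-like structures lie in fibrous tissue) were profiled, with 4 arrays per tissue at 0.92 mg per kg body weight and 5 per tissue at 2 mg. Each of the 32 arrays gave an intensity for 62976 features. The design asks how each tissue differs from control liver, how lesion and non-lesion tissue differ within a dose, and whether the dose matters.

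The first principal component of the 31488 features at or above the median level held 59.4% of the variance and ran from non-lesion tissue towards lesion tissue. Tissues were not fully separated on it, because TRT 2 mg replicate 5 lay at -7.97, below control replicate 4 at 81.8. TRT 0.92 mg replicate 1 and TRT 2 mg replicate 3 lay farthest out, at 266.8 and 286.1, where no other array passed 91.0. The second component held 12.1% and set apart 8 arrays that were replicates 3 and 4 of control and of NT, ANT and TRT at 0.92 mg. They lay between -82.5 and -34.0, and the other 24 lay between -9.70 and 81.9. No array at 2 mg was among the 8, and the labels name no slide or date that the set could be matched to. For this reason the comparisons that involve control or 0.92 mg arrays were also made with the set as a block and inside and outside it.

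**Figure D1:**
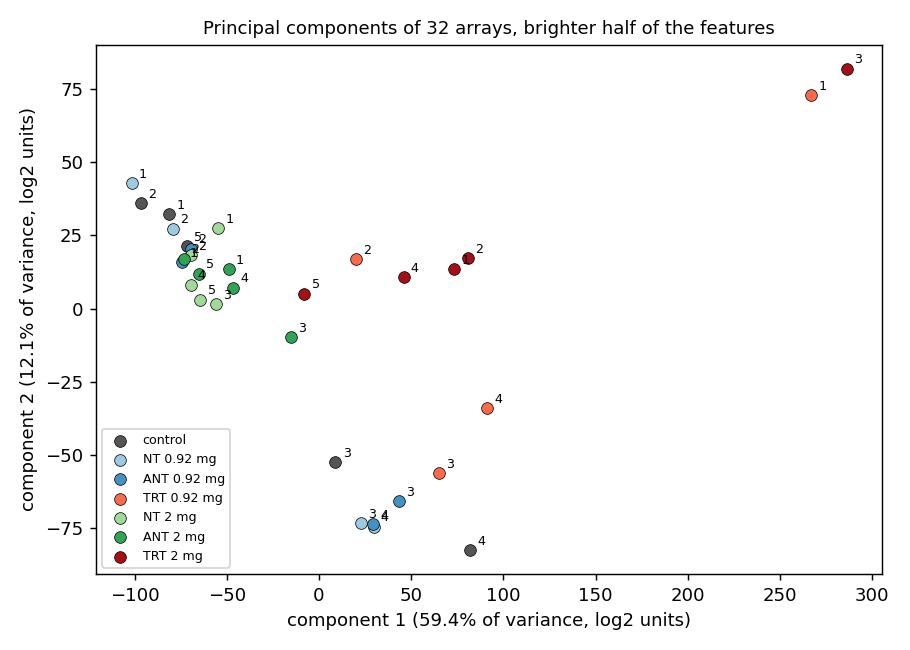
Scores of the 32 arrays on the first (horizontal) and second (vertical) principal components of the log2 values of 31488 features, with colours for the 7 groups and replicate numbers beside the points. The components hold 59.4% and 12.1% of the variance, and 8 arrays lie at or below -34.0 on the second one.

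Lesion tissue differed from control liver by many features that were higher in TRT. At 2 mg, 1913 features were higher and 377 lower in TRT (n = 5) than in control (n = 5), and at 0.92 mg 1234 were higher and 1 lower (n = 4 against 5). Of the calls, 1878 higher and 235 lower features at 2 mg, and 1234 and 0 at 0.92 mg, differed at least 2-fold. Feature 47675 had an intensity of 44146 ± 38177 (SD, n = 5) in TRT at 2 mg and 34301 ± 35203 (SD, n = 4) at 0.92 mg, against 14.5 ± 19.7 (SD, n = 5) in control. With the plateau at 20 this is at least 1146-fold higher at 2 mg (limma adjusted p = 0.000343) and at least 935-fold higher at 0.92 mg (limma adjusted p = 0.00121). Feature 16452 had 22838 ± 20739 (SD, n = 5) in TRT at 2 mg and 6.42 ± 3.69 (SD, n = 5) in control, at least 713-fold higher (limma adjusted p = 0.000336). Among the features that met the rule for single features, 7740 and 43145 had the largest falls at 2 mg. Feature 7740 had 1389 ± 654 (SD, n = 5) in TRT and 7892 ± 2950 (SD, n = 5) in control, a log2 difference of -2.60 ± 0.38 (SE, limma adjusted p = 0.00458). Feature 43145 had 173 ± 60.2 (SD, n = 5) against 1034 ± 318 (SD, n = 5), a log2 difference of -2.59 ± 0.31 (SE, limma adjusted p = 0.00173). At 0.92 mg neither fall was called, with log2 differences of -1.86 and -2.02 (limma adjusted p = 0.0630 and 0.240), except without TRT replicate 3 (-2.17 and -2.69, limma adjusted p = 0.0269 and 0.0490, the lowest over 19 settings each). Groups did not overlap for 5.85% of all features at 2 mg and 6.62% at 0.92 mg, where chance gives 0.794% and 1.59%.

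The size and balance of these counts depended on scaling and on single arrays. Relative to control, the median of all features was -0.19 on the log2 scale in TRT at 2 mg, and median centring moved it to -0.53 and the calls to 1894 higher and 1534 lower. Quantile normalization gave 1533 higher and 718 lower. With the set of 8 arrays as a block, 4448 features were higher and 1850 lower at 2 mg, and with only arrays outside the set 4163 and 1739. At 0.92 mg the block gave 1097 higher and 1 lower, the arrays outside the set 521 and 0, and the arrays inside it, 2 against 2, 600 and 17. At 2 mg the 2290 calls became 1244, 1408, 3673 and 1244 without control replicate 1, 2, 4 or 5, and 1261, 1156, 1491 and 3712 without TRT replicate 1, 2, 4 or 5. At 0.92 mg the 1235 calls became 597, 646 and 619 without control replicate 1, 2 or 5, and 784 and 408 without TRT replicate 2 or 4.

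**Figure D2:**
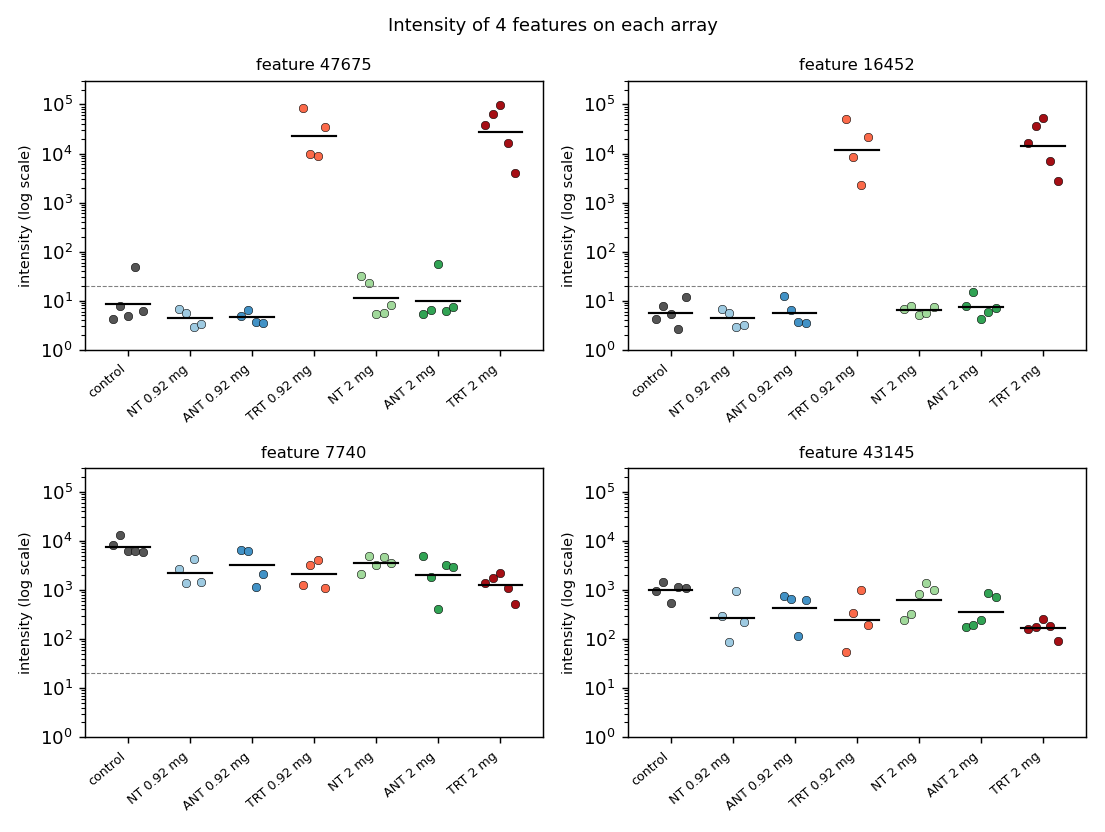
Intensity (log axis) of features 47675, 16452, 7740 and 43145 on each array, with a column of points per group, the geometric mean as a bar and the plateau level of 20 as a dashed line. Features 47675 and 16452 lay at or above 2236 on all 9 TRT arrays and at or below 55.4 on the other 23.

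Liver without a lesion differed little from control liver in the number of features called. No feature was called by limma in NT at 0.92 mg (1004 at an unadjusted p under 0.05), in NT at 2 mg (3767) or in ANT at 0.92 mg (697) against control. Groups did not overlap for 1.54% of features in NT and 1.76% in ANT at 2 mg, above the 0.794% that chance gives. At 0.92 mg the shares were 0.888% and 0.476%, below the 1.59% that chance gives. ANT at 2 mg had 10 features higher and 3 lower than control. Under the rule for single features, its largest rises were in a pair of features that ran together. They had 4540 ± 3046 and 4590 ± 3139 (SD, n = 5) in ANT against 207 ± 88.3 and 211 ± 83.0 (SD, n = 5) in control. These are log2 differences of 4.35 and 4.32 (limma adjusted p = 0.0105 for both). The same features had means of 2729 and 2926 in NT and 1366 and 1373 in TRT at 2 mg. By the means of the log2 values, NT at 2 mg was 10.4-fold and 10.8-fold above control without passing the threshold (limma adjusted p = 0.310 for both). The largest fall in ANT under the same rule was in a feature with 544 ± 142 (SD, n = 5) against 1555 ± 182 (SD, n = 5) in control. It was 2.92-fold lower by the means of the log2 values (limma adjusted p = 0.0341).

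The 13 calls of ANT at 2 mg became 81 with the set of 8 arrays as a block, of which 67 were higher and 14 lower, and 128 with only arrays outside it, of which 87 were higher and 41 lower. All 13 were among both. They became 4, 42, 0, 40 and 0 without control replicate 1, 2, 3, 4 or 5, and 24, 25, 0, 2 and 0 without ANT replicate 1, 2, 3, 4 or 5. With the set as a block, limma gave 0 calls for NT at 0.92 mg (2659 at an unadjusted p under 0.05), NT at 2 mg (4383) and ANT at 0.92 mg (1726). With only arrays inside the set, 2 against 2, NT at 0.92 mg had 19 calls and ANT 2. With only arrays outside it, the same 3 comparisons had 0 calls by limma (2194, 5248 and 1915). Without control replicate 2, NT at 2 mg and ANT at 0.92 mg had 2 calls each.

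ANT and NT could not be told apart by single features at either dose. No feature was called by limma at 0.92 mg (276 at an unadjusted p under 0.05) or at 2 mg (625), and the block of replicate numbers also gave 0 calls at both doses, with 2317 and 1925 features at an unadjusted p under 0.05. At 0.92 mg the set of 8 arrays as a block and the arrays inside it gave 0 calls, and the arrays outside it, 2 against 2, gave 2.

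Lesion tissue and non-lesion tissue of furan-treated rats differed by 5779 features higher and 3978 lower in TRT than in NT at 2 mg (n = 5 each). At 0.92 mg 999 were higher and 2 lower (n = 4 each). At 2 mg the median log2 rise of the called features was 2.02, and 5253 higher but only 664 lower features differed at least 2-fold. Feature 47675 was at least 1222-fold higher in TRT than in NT at 2 mg (limma adjusted p = 0.000240) and at least 1121-fold higher at 0.92 mg (limma adjusted p = 0.000900). Its intensity in NT was 14.7 ± 11.9 (SD, n = 5) and 4.67 ± 1.82 (SD, n = 4). Feature 16452 was at least 713-fold higher at 2 mg (limma adjusted p = 0.000151) and at least 595-fold higher at 0.92 mg (limma adjusted p = 0.00152). At 0.92 mg both calls were lost with only arrays outside the set of 8, and that of 16452 also inside it. The highest limma adjusted p over 19 settings was 0.228 for each. Features 7740 and 43145 were lower in TRT than in NT at 2 mg by log2 differences of -1.52 ± 0.37 (SE, limma adjusted p = 0.0228) and -1.90 ± 0.48 (SE, limma adjusted p = 0.0247). The samples of TRT and NT overlapped for both features. The call of 7740 was lost without NT replicate 2, 4 or 5 (limma adjusted p = 0.0601, 0.0587 and 0.0520), in 1 fit of all arrays (0.0577) and with quantile normalization (0.0607), and its adjusted p ranged from 0.00230 to 0.0607 over 18 settings. The call of 43145 was lost without TRT replicate 1 or 2 (0.0541 and 0.0555), without NT replicate 3, 4 or 5 (0.0567, 0.0543 and 0.0611), in 1 fit of all arrays (0.0534) and with a floor at 20 that kept all features (0.0518), and ranged from 0.00462 to 0.0611. At 0.92 mg the differences between TRT and NT were -0.09 and -0.14 (limma adjusted p = 0.929 and 0.937), and their direction changed with the setting. Groups did not overlap for 14.9% of features at 2 mg and 7.81% at 0.92 mg, where chance gives 0.794% and 2.86%.

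Some features were off in 1 tissue and on in the other. At 2 mg, 91 features lay below 20 on all NT arrays and at or above 100 on all TRT arrays, and at 0.92 mg there were 99. None went the other way. Against control the numbers were 57 and 60, and against ANT 42 and 53, with none the other way. In every one of these 6 comparisons the number at the level of 100 was larger than in any other split of the same arrays, of which there were 126 or 35 with the real one, the highest being 9. For TRT against ANT at 2 mg these splits ignore the pairs, and the 16 splits that part all pairs are too few for a share under 0.05. The same limit holds for TRT against NT at 2 mg if its numbers pair too. Over both doses, 37 features were on in all 9 TRT arrays and off in all 14 control and NT arrays. Of these, 20 were also off in all ANT arrays, and 1 reached 100 in an ANT array. Their mean intensities in TRT had a median of 1836. Taken on geometric means and against the plateau at 20, the lower bounds of their folds had a median of 56.3.

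The split into higher and lower features at 2 mg moved with the scaling. Relative to NT, the median of all features in TRT was -0.29 on the log2 scale as scaled here, -0.12 after quantile normalization and -0.74 after median centring. Quantile normalization gave 4385 higher and 4136 lower features, and median centring 5298 and 32861. Without a change of scaling, the dim filter turned the balance to 4972 higher and 5221 lower. At 0.92 mg quantile normalization gave 182 higher features and 1 lower, and replicate numbers as a block 71 higher and 0 lower. At 2 mg the 9757 calls became 5551, 4701 and 28562 without TRT replicate 1, 2 or 5, and 4944, 6299, 5121 and 5552 without NT replicate 2, 3, 4 or 5. Of the 28562, 19586 were lower in TRT. At 0.92 mg the 1001 calls became 277, 318, 600 and 327 without NT replicate 1, 2, 3 or 4, and 448 and 190 without TRT replicate 2 or 4. The set of 8 arrays as a block gave 675 higher and 3 lower features at 0.92 mg. Inside the set, 2 against 2, there were 382 higher features, and outside it, with 11103 features at an unadjusted p under 0.05, none was called by limma.

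TRT was also compared with the adjacent tissue. At 2 mg 3626 features were higher and 1420 lower in TRT than in ANT (n = 5 each), and at 0.92 mg 531 were higher and 0 lower (n = 4 each). Feature 47675 was at least 1121-fold higher in TRT than in ANT at both doses (limma adjusted p = 0.000527 at 2 mg and 0.00208 at 0.92 mg), and its intensity in ANT was 16.1 ± 21.9 (SD, n = 5) at 2 mg. At 0.92 mg this call was lost with replicate numbers as a block (limma adjusted p = 0.139) and with only arrays inside or outside the set of 8 (0.0634 and 0.224, the highest over 19 settings, with 8.43e-10 the lowest). Features 7740 and 43145 were not called lower in TRT than in ANT at 2 mg, with log2 differences of -0.71 and -1.08 (limma adjusted p = 0.403 and 0.112), except 43145 with median centring (-1.45, limma adjusted p = 0.0330, where 18 settings ranged from 0.0330 to 0.238). In ANT at 2 mg they differed from control by -1.88 and -1.51, also without passing (limma adjusted p = 0.492 and 0.527). With replicate numbers as a block, 7275 features were higher and 17020 lower at 2 mg, and 5042 of the 5046 features were called in the same direction in both fits. At 0.92 mg, where the numbers did not pair the samples, the same block left 0 calls by limma (13342 at an unadjusted p under 0.05). Quantile normalization gave 2097 higher and 1115 lower features at 2 mg and 21 higher at 0.92 mg, and median centring gave 4774 higher and 27143 lower at 2 mg.

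At 2 mg the 5046 calls of TRT against ANT became 1709, 1516, 1577 and 1490 without ANT replicate 1, 2, 4 or 5, and 1654, 1252, 2927 and 27319 without TRT replicate 1, 2, 4 or 5. At 0.92 mg the 531 calls became 41, 45 and 43 without ANT replicate 1, 2 or 4, and 937, 73, 921 and 17 without TRT replicate 1, 2, 3 or 4. With the set of 8 arrays as a block there were 173 calls at 0.92 mg, all higher in TRT, with 35 inside the set and 0 outside it (6397 at an unadjusted p under 0.05).

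**Figure D3:**
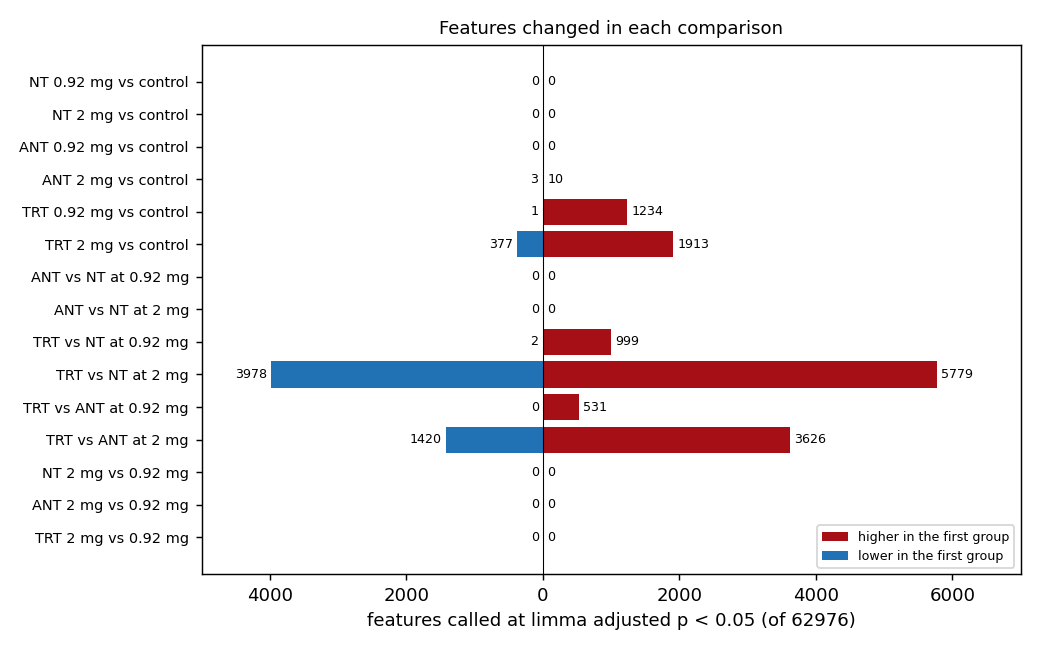
Number of features called by limma in each of 15 comparisons, with features higher in the first-named group to the right and lower ones to the left of 0. The largest bars belong to TRT against NT at 2 mg, with 5779 features higher and 3978 lower in TRT.

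Lesions at the 2 doses did not differ by any called feature. TRT at 2 mg against TRT at 0.92 mg gave 0 calls by limma (639 at an unadjusted p under 0.05), NT gave 0 (3892) and ANT gave 0 (4026). The interaction of dose with the difference between TRT and NT gave 0 calls as well (370). The larger number of calls at 2 mg in the comparison of TRT with NT was therefore not matched by a tested difference between doses. With the set of 8 arrays as a block, NT had 1 call, ANT 2 and TRT 0 between doses, and with only arrays outside it 5, 0 and 0. NT also had 4 calls without its 0.92 mg replicate 1 or 3, and ANT had 4 without its 2 mg replicate 4.

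The lesion differences of both doses, which share no array, ran together. Of the 999 features higher in TRT than in NT at 0.92 mg, 956 were also called higher at 2 mg, where 91.7 would be shared by independent lists. Neither of the 2 features lower at 0.92 mg, both below 20 on average in TRT and NT, was called lower at 2 mg (0.126 for independent lists). Of the 3978 features called lower at 2 mg, 3930 had a lower mean at 0.92 mg too, and of the 5779 called higher, 5769 had a higher one. At 0.92 mg the median log2 difference of all features between TRT and NT was -0.18, so a lower mean was common there under this scaling. The median log2 difference of the features called higher at 2 mg was 2.02 at that dose and 1.68 at 0.92 mg. Across all 62976 features, which are not independent replicates, the log2 differences at both doses had a Pearson r of 0.931 and a Spearman rho of 0.834. Each dose holds 1 of the 2 TRT arrays that lay farthest out. Without TRT 0.92 mg replicate 1 the Pearson r was 0.878, the lowest when 1 array was left out. The 956 shared features became 268, 310, 577 and 320 without NT 0.92 mg replicate 1, 2, 3 or 4, and 441 and 185 without TRT 0.92 mg replicate 2 or 4. They were 69 with replicate numbers as a block, 161 with quantile normalization, 433 with the dim filter, 394 and 169 with the 2 versions of a floor at 20, and 2417 in 1 fit of all arrays. They were 641 with the set of 8 arrays as a block at 0.92 mg, 374 with its arrays alone and 0 without them.

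**Figure D4:**
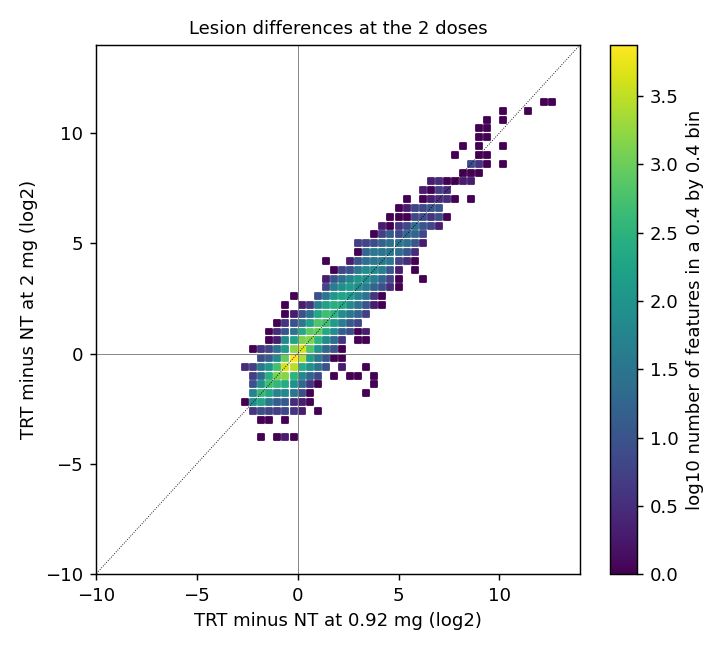
Log2 difference between TRT and NT at 0.92 mg (horizontal) and 2 mg (vertical) for the 44118 features with a mean intensity of at least 20 in 1 of the 4 groups, as the log10 number of features per bin, with a dotted line where both are equal. The Pearson r across these features was 0.948.

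The share of the summed intensity in the brightest 1% of features was 46.0% ± 3.2 (SD, n = 5) in control, 47.4% ± 1.7 (SD, n = 5) in NT, 47.8% ± 1.0 (SD, n = 5) in ANT and 43.8% ± 1.5 (SD, n = 5) in TRT at 2 mg. At 0.92 mg it was 45.8% ± 4.3 in NT, 46.1% ± 4.5 in ANT and 42.8% ± 2.1 in TRT (SD, n = 4 each). TRT at 2 mg was lower than ANT by 3.95 percentage points (exact 2-sided permutation p = 0.00794, 0.119 after Benjamini-Hochberg adjustment over 15 comparisons) and lower than NT by 3.60 points (exact permutation p = 0.0238, 0.179 adjusted). These permutations ignore the pairs that the numbers mark for TRT and ANT at 2 mg, and that would follow for TRT and NT. Within the pairs of TRT and ANT, TRT was lower in 5 of 5 (exact 2-sided sign-flip permutation p = 0.0625, the smallest that 5 pairs can give). TRT and NT were not tested in pairs. No comparison passed the adjustment.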

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

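The tests of scaling for the 8 arrays and for the balance of calls, of noise and of lesion tissue in the far arrays and both tests of the low plateau were chosen after the patterns they test had been seen, as was the set of 8 arrays itself.

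Of 63 sets of values from a group of 4 or 5 arrays, 5 held an array far from the others, where chance gives about 1 in 20, or 3.15 here. ANT 2 mg replicate 2 had 38.9% of its features below 20, against 36.7% to 36.9% in the other ANT arrays at that dose. Feature 47675 had an intensity of 49.7 in control replicate 4, against 4.26 to 7.65 in the other controls, and 55.4 in ANT 2 mg replicate 3, against 5.47 to 7.37. TRT 0.92 mg replicate 1 had a mean correlation of 0.902 with the other arrays, against 0.961 to 0.970 in the other TRT arrays at its dose. TRT 2 mg replicate 3 had 0.895, against 0.957 to 0.971.

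The last 2 arrays form the first pattern. Their deviations from the mean of the other TRT arrays of their dose correlated at 0.825 across features, against -0.200 to 0.199 in the 12 pairs of other TRT arrays from both doses, which argues against noise separate to each array. Of the features at least 2-fold from NT in the TRT arrays of the other dose, without the far array there, 98.8% of the higher and 77.5% of the lower ones lay farther the same way in TRT 0.92 mg replicate 1 than in the other TRT arrays of its dose, and 98.5% and 76.8% did in TRT 2 mg replicate 3. The lower features missed the 80% that was asked of all 4 shares, and TRT 2 mg replicate 1 had similar ones (92.3% and 77.9%). By these shares, a larger amount of the same lesion tissue cannot be told apart from other sources. The median log2 shifts of the far arrays were larger, at 1.79 and 1.90 for the higher and -1.05 and -0.645 for the lower features. No other TRT array passed the 0.840 and -0.504 of TRT 2 mg replicate 2. RNA quality stays untested, and no group of the design separates the 2 arrays.

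The second pattern is the set of 8 arrays, and after quantile normalization all 8 were still the lowest on the second component, which argues against the scaling. Of the 91 features that were off in NT and on in TRT at 2 mg, 23.1% and 29.7% were at or above 20 in control replicates 3 and 4, and 13.2% and 12.1% in NT 0.92 mg replicates 3 and 4, against at most 7.69% in the other 5 such arrays. Of these 4, only control replicate 4 lay above the bound under which all had to lie to argue against lesion tissue, so for the set as a whole lesion tissue cannot be told apart from other sources because of that array. In all, 3057 features were higher in the 6 non-lesion arrays of the set than in all 17 other non-lesion arrays. Of these, 49.3% were called higher in TRT than in NT at 2 mg, against 9.18% of all features. The NT arrays at 2 mg are among those 17 and are also the reference of that call. Choosing features that are low in them can by itself raise this share, so it says nothing about lesion tissue in the set. A shared slide or labelling day is a candidate explanation that the labels do not allow to be tested, and no biological explanation other than lesion tissue was tested.

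The third pattern is the balance of calls in TRT against NT at 2 mg, of which 59.2% were higher, against 48.8% with the dim filter and 31.4% without TRT replicate 5. With quantile normalization it was 51.5%, with 48.7% and 46.6% without TRT replicate 3 or 5 and up to 67.2% without another array. This test cannot tell the scaling apart from other sources of the balance. With median centring, which moves all features of an array alike as the main scaling does, it was 13.9%. The balance therefore depended on the scaling, and no test here tells which scaling is right. Of the 3978 lower calls, 90.7% had all 10 arrays at or above 20, which argues against values on the low plateau as their source. With values below 20 set to 20, the number of lower calls was 119% of that without the floor if features at the floor on every array were left out and 78.4% if they were kept, so how far the plateau changes their number stays open. The rise in the median intensity of TRT arrays that median centring removes was not tested for a biological origin.

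Other splits of the same arrays were counted for every comparison, up to 100 splits with the real one included. For TRT against NT and against ANT at 0.92 mg, 1 of 35 splits gave as many calls in each. The real splits gave 1001 and 531 calls, against at most 310 and 153 in the others. This share is under the 0.05 set beforehand, which argues against chance for both. It is also the smallest that 35 splits can give and was not adjusted over the comparisons, so chance is not excluded. Those highest other splits set replicates 1 and 2 apart from 3 and 4, which follows the set of 8 arrays. For TRT against control, 4 of 100 splits at 0.92 mg and 3 of 100 at 2 mg gave as many calls, with 1235 and 2290 calls and at most 23401 and 22839 in the others. For TRT against NT at 2 mg it was 3 of 100, with 9757 calls and at most 19191, in splits that ignore any pairing by number. For ANT 2 mg against control it was 2 of 100, with 13 calls and at most 144, in a split that put ANT replicates 1 and 2 with control replicates 1, 2 and 3. The share of splits lay under the 0.05 set beforehand for each of these, without adjustment over the comparisons. Since other splits gave more calls than the real ones, chance is not excluded. The highest others point to a structure of the samples. At 0.92 mg the highest put control replicate 4 with TRT replicates 1, 3 and 4. At 2 mg each of the highest of TRT put TRT replicate 5 with non-lesion arrays. For TRT against ANT at 2 mg, where numbers pair the samples, the real split gave 5046 calls and the others of the 16 splits that part all 5 pairs gave 0, but 16 splits are too few for a share under 0.05. Of splits that ignore the pairs, 2 of 100 gave as many, with at most 22803, again with TRT replicate 5 among non-lesion arrays.

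Every split gives at least 0 calls, so for comparisons with 0 calls the splits say nothing about chance. This was 100 of 100 splits for NT and ANT at 0.92 mg and NT at 2 mg against control, for ANT against NT at 2 mg, for the 3 comparisons between doses and for the interaction, and 35 of 35 for ANT against NT at 0.92 mg. The highest other split gave 28250 calls for NT and 16243 for ANT at 0.92 mg against control, and 34740 for ANT against NT at 0.92 mg. Each of these 3 splits parted the set of 8 arrays from the rest, and the value with the set as a block was 0 calls in all 3. The highest others were 134 for NT at 2 mg against control, 9170 for ANT against NT at 2 mg, 13655, 12075 and 1082 for NT, ANT and TRT between doses, and 7205 for the interaction, which points to a structure of the samples in these too. In the splits that part all pairs of ANT and NT, 8 at 0.92 mg and 16 at 2 mg, which are too few for a share under 0.05, none gave a call.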

How the results depend on the processing

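Both versions of a floor at 20, the set of 8 arrays, the removal of 2 lesion arrays, the levels for on features, the sizes of the brightest class and all settings of the lesion score were chosen after seeing the data. Apart from the scaling itself, the cause of the changes was not tested. The mean over a gene's probes and the gene lists were not run, since features have no gene names here. Signal over background is not known per feature, and 33.1% to 38.9% of features per array lay on the low plateau.

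Counts of TRT at 0.92 mg moved with most settings. Against control (1235), they were 4148 in 1 fit of all arrays, 617 with quantile normalization, 628 with the dim filter, 762 with the floor when features at the floor were left out and 234 when they were kept, 521 outside and 617 inside the set of 8 arrays. Against NT (1001), they were 2516, 183, 436, 400 and 173 in the first 5 of these settings, 71 with the replicate block, 0 outside and 382 inside the set. Against ANT (531), they were 1839, 21, 111, 81 and 24, then 0 with the replicate block, 173 with the set as a block, 0 outside and 35 inside it, and 937 without both far lesion arrays. Beside the counts of 0 by limma, 11103 (TRT against NT outside the set), 13342 (TRT against ANT, replicate block) and 6397 (TRT against ANT outside the set) had an unadjusted p under 0.05.

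At 2 mg, TRT against control (2290) had 6019 calls in 1 fit of all arrays, 1180 with the floor that kept all features, 6298 with the set as a block and 5902 outside it. TRT against NT (9757) moved by over 1.5 times with median centring, to 38159, and otherwise only when 1 array was left out; with the floor it was 10086 or, with all features kept, 6711. TRT against ANT (5046) had 3212 with quantile normalization, 31917 with median centring, 1779 with the floor that kept all features and 24295 with the replicate block. ANT against control (13) had 28 in 1 fit of all arrays, 4 with the dim filter, 6 with the floor that left features out and 0 by limma with the one that kept them (3776 at an unadjusted p under 0.05), 81 with the set as a block and 128 outside it. The features shared by both doses (956) were 2417 in 1 fit of all arrays, 161 with quantile normalization, 433 with the dim filter, 394 and 169 with the floor, 69 with the replicate block, and 0 outside and 374 inside the set.

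Counts of 0 became 7 with quantile normalization and 1 with the floor that left features out in NT 2 mg against control, 19 in NT and 2 in ANT 0.92 mg against control inside the set, and 2 in ANT against NT at 0.92 mg outside it. Between doses, NT had 2 with quantile normalization, 1 with the set as a block and 5 outside it, and ANT had 2 with the set as a block. TRT between doses and the interaction had 0 by limma under every setting run for them, with 639 and 370 at an unadjusted p under 0.05 as scaled here.

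Leaving out 1 array gave 0 to 2 calls in NT 2 mg and in ANT 0.92 mg against control, and 0 to 42 in ANT 2 mg against control. TRT against control ranged from 408 to 1502 at 0.92 mg and from 1156 to 3712 at 2 mg, TRT against NT from 190 to 1386 and from 4701 to 28562, and TRT against ANT from 17 to 937 and from 1252 to 27319. NT and ANT between doses ranged from 0 to 4, and the shared features from 185 to 1329. The other comparisons had 0 throughout.

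TRT and NT do not meet the rule for paired numbers. Correlations ran from -0.148 to 0.552 at 0.92 mg, where 3 of 4 TRT arrays correlated best with their own number. They ran from 0.0339 to 0.237 at 2 mg, where 4 of 5 did. At 2 mg, pairs of ANT with NT and of TRT with ANT would still imply pairs of TRT with NT. TRT and ANT at 0.92 mg do not meet the rule either, from -0.223 to 0.517, with 3 of 4.

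The direction of 2 uncalled differences between TRT and NT at 0.92 mg changed. Feature 7740 (-0.09) rose by 0.0018 with quantile normalization, 0.0733 outside the set, 0.15 without both far arrays or without TRT replicate 1, 0.01 and 0.24 without NT replicate 1 or 3, and 0.21 without TRT replicate 4, with -0.40 the lowest value when 1 array was left out. Feature 43145 (-0.14) rose by 0.58 without both far arrays or without TRT replicate 1, and by 0.46 without NT replicate 3, with -0.81 the lowest. Between TRT and ANT at 0.92 mg, the uncalled differences of both features (-0.63 and -0.83) became 0.42 and 0.71 inside the set. Over the 4 features in 6 comparisons of TRT with control, NT and ANT, 410 values under other settings kept direction and side of the threshold, 23 lost their call, 3 gained one and 12 changed direction. At 0.92 mg features 47675 and 16452 lost their calls against ANT with the replicate block, outside the set and inside it, with log2 differences of at least 10.90. Against control and NT they lost them only inside or outside the set, where fewer arrays are compared and log2 differences were still 10.13 and 10.87 against control inside it, 12.19 and 11.69 against NT outside it and, for 16452, 11.13 against NT inside it.

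With 2000 features per direction the lesion score lost its calls of TRT against control, with differences of 2.62 at 0.92 mg and 2.38 at 2 mg (exact permutation p = 0.0686 and 0.0635 after adjustment), and the uncalled score difference of ANT 2 mg and control went from 0.08 to -0.16. The share of signal in the brightest 2% was lower in ANT 0.92 mg than in control by -0.104 points, while that in the brightest 1% was higher by 0.168, and neither passed. With the level for on at 50 and at 200 in place of 100, the 91 features on in TRT but off in NT at 2 mg became 212 and 45. The Pearson r between doses ranged from 0.745, with only the 0.92 mg arrays of the set, to 0.964 with the dim filter.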

Other observations

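The lesion score, its tests and the description of a pair of features were chosen after seeing the data. The score was the mean log2 level of 500 features highest in TRT against NT by limma, minus that of 500 lowest, with the features taken from the other dose so that no array was scored by features chosen on it, except controls, which chose none. Of 31488 features at or above the median, the sets of both doses shared 291 raised and 39 lowered features, where independent sets share 7.94. TRT at 2 mg scored -0.56 ± 1.56 (SD, n = 5), against -4.95 ± 0.32 in NT, -4.41 ± 0.61 in ANT and -4.49 ± 0.85 in control (SD, n = 5 each). TRT was above all arrays of each of these groups in 5 of 5 arrays, by 4.39, 3.85 and 3.94 (exact 2-sided permutation p = 0.00794 for each, the smallest these arrays can give, 0.0238 after Benjamini-Hochberg adjustment over 12 tests). Taken in the pairs that the numbers mark at 2 mg, TRT was above ANT in 5 of 5, but 5 pairs cannot pass (exact sign-flip permutation p = 0.0625, the smallest possible). TRT against NT at 2 mg was not tested in pairs, and the same limit would apply if its numbers pair. At 0.92 mg TRT scored -0.62 ± 1.43 (SD, n = 4), above NT by 3.82 and above ANT by 3.46 (exact permutation p = 0.0286 for both, the smallest possible, 0.0571 adjusted) and above control by 3.90 (exact permutation p = 0.00794, 0.0238 adjusted), in 4 of 4 arrays. The 6 tests without TRT gave exact permutation p-values from 0.103 to 0.865. At 0.92 mg TRT exceeded control by 2.16 inside the set of 8 arrays and by 5.23 outside it, NT by 2.47 and 5.18, and ANT by 1.95 and 4.96. At 2 mg, TRT exceeded control by 4.53 with only arrays outside the set. The uncalled difference of NT and control changed direction, from 0.08 to -0.30 inside the set at 0.92 mg and from -0.45 to 0.14 outside it at 2 mg, and that of ANT and control at 2 mg went from 0.08 to 0.68 outside it. These differences inside and outside the set were not tested.

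A hypothesis was that adjacent tissue carries part of the lesion profile. ANT scored above its same-numbered NT sample in 6 of 9 pairs over both doses, 4 of 5 at 2 mg and 2 of 4 at 0.92 mg, which leaves it open. The mean difference was 0.54 at 2 mg (exact sign-flip permutation p = 0.188, where 5 pairs cannot go below 0.0625) and 0.37 at 0.92 mg (exact sign-flip permutation p = 0.500, with 0.125 the smallest possible). Inside and outside the set of 8 arrays the difference at 0.92 mg was 0.51 and 0.22. Single ANT arrays held more of the lesion features: of the 91 features off in NT and on in TRT at 2 mg, 58.2% were at or above 20 in ANT 2 mg replicate 3 and 50.5% in ANT 0.92 mg replicate 3, against 4.40% to 26.4% in the other ANT arrays. The median intensity of the 91 features was 26.2 in ANT 2 mg replicate 3 and 20.1 in ANT 0.92 mg replicate 3, near the floor of 20. In TRT arrays it ran from 207 to 3620. The NT arrays at 2 mg hold 0% by the choice of these features. ANT 0.92 mg replicate 3 belongs to the set of 8 arrays, in which control replicates 3 and 4 held 23.1% and 29.7%. In NT 0.92 mg replicates 3 and 4 the shares were 13.2% and 12.1%.

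The pair of features with the largest rises in ANT at 2 mg, under the rule for single features, had means of 207 and 211 in control. At 0.92 mg the means were 581 and 609 in NT and 1081 and 1155 in ANT. At 2 mg they were 2729 and 2926 in NT and 4540 and 4590 in ANT. In TRT the means were 445 and 443 at 0.92 mg and 1366 and 1373 at 2 mg. At 2 mg TRT ranged from 2.99 to 2759 for the first of the pair. The difference between doses in ANT did not pass (limma adjusted p = 0.514 for both).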
